A study of Drosophila melanogaster with 8 samples.

How the data were processed

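The FPKM values of 8 libraries were deposited by the authors, made with Cufflinks on reads aligned to the Drosophila melanogaster genome, build dm3. Per the submitters' processing notes the tools were Bowtie, Bowtie2, TopHat 0.6 and Cufflinks. Their order and options, and the versions of the others, are not given in the sources used here. Per the labels' protocols, libraries were made with the TruSeq kit from polyA RNA after Ribo-Zero removal of ribosomal RNA. Each library listed 15296 gene models with an FPKM, its confidence bounds and a status. The log2 ratios of A4 to A12 in a further table were deposited by the authors for 9120 genes. For the 8344 tested genes in it, 100.0% of the finite ratios lay within 0.01 of the log2 ratio of the group means of the deposited FPKM, with medians of -0.56 in larvae and -0.06 in adults. It gave finite ratios where a group mean was 0 for 166 genes in larvae and 87 in adults.

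Genes with a failed or high-data status in any library, 17 in all, were removed. Genes with a mean of at least 1 FPKM over the 8 libraries were tested, 9679 genes, on log2(FPKM + 1). Of all symbols, 105 stood at more than 1 locus and were kept as separate loci. Of the tested genes, 317 were small RNA genes and 1144 had an exact 0 in at least 1 library. Differences were tested with limma 3.58.1 in R 4.3.3, by 1 fit of the 4 groups with eBayes and a mean-variance trend, and p-values were adjusted by Benjamini and Hochberg at 0.05. All adjusted p-values of genes came from this fit unless an alternative is named, and those of gene lists from the camera test in limma with its preset correlation. The preset was set against a correlation estimated from the residuals. For lipid and sugar metabolism genes in larvae the estimate, 0.00507, was below the preset, yet the camera adjusted p rose from 1.17e-05 to 0.183. The 2 runs therefore differ in more than the correlation. Over the 25 lists, however, the estimate ran from -0.0236 for glue and Eig71E genes to 0.717 for genes on chromosome 4. It was 0.662 for genes residing in pericentromeric heterochromatin. A call lost with the estimate can thus rest on the correlation, on the other difference or on both, and the loss is not set aside. Tests of overlap and of chromosomes were two-sided Fisher's exact tests, and windows of 11 neighbouring genes were tested by permuting calls. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6.

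The comparisons, the alternatives and the rule for named genes were chosen before the data were examined. For each genotype comparison the rule took the 12 genes with the largest change up and the 12 with the largest down, among those past the threshold whose libraries did not overlap between genotypes, and 6 each way for each stage comparison. It added up to 10 genes past the threshold at both stages, up to 4 members of each gene list with the smallest p, and the genes of the window with the most calls with up to 6 neighbours. From the authors' table it took the 5 largest and 5 smallest ratios of each comparison. The genes w, lt, rl, Su(var)3-9 and that of HP1a were chosen in any case, and the interaction was read from its 8 smallest adjusted p-values. Mcm10 with its neighbours bur and clumsy, roX1, roX2, Mst84Dc and ocn were added after their values were seen. The 25 gene lists were written by gene function from general knowledge. They overlap in places, so that the dopamine genes Ddc and ple sit with neuronal genes.

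The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median centring, quantile normalization, eBayes without trend, robust eBayes, a fit of only the compared groups, replicate number as a block, each library left out in turn, and other thresholds. Chosen after seeing the data were fits without genes listed at 0 in any library, without small RNA genes, and with the replicate block on centred values. Methods for read counts, such as the size factors of DESeq2 or TMM of edgeR, do not apply to FPKM. Replicate numbers did not pair libraries across groups, since the correlations of replicate 1 minus 2 between groups lay from -0.062 to 0.086. Strand and read counts were not used here.

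The fit was tested on simulated data in which, for each size of change, 50 genes of 9679 were changed. In larvae changes of 0.5, 1, 2 and 3 on the log2 scale were found in 0%, 12%, 78% and 96% of genes with 2 false calls. In adults they were found in 0%, 14%, 66% and 92% with 6 false calls. The simulated noise was independent between genes and had the same spread in every group, and most genes were unchanged. These rates therefore do not test the spread shared by the groups. They may not hold for the larval data, where 34.7% of genes were called. Small RNA genes made up 61.44% to 80.31% of the FPKM sum of a library.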

Results

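RNA from whole Drosophila melanogaster females was sequenced at 2 stages, third-instar larvae and adults aged 2 to 3 days, all raised at 18 °C. A4/A4 females are homozygous for In(2)A4, an inversion of chromosome 2. The series presents the rearranged animals as showing position effect variegation, the patchy silencing of genes that a rearrangement places next to heterochromatin. A12/A12 females stood for the wild type of that design. The 4 groups, A4 larvae, A12 larvae, A4 adults and A12 adults, held 2 libraries each, 8 in all. Expression was given as FPKM, mapped fragments scaled to the length of the gene model and to the size of the library. Below, a level is the mean FPKM ± SD (n = 2), and a log2 change is a difference on the log2(FPKM + 1) scale ± its standard error. Positions are in build dm3, counted from 1.

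The deposited values carried no read counts, so the absolute depth was unknown. Relative to A4 larvae replicate 1, the depth read from the confidence bounds of weakly expressed genes ran from 0.96 in A4 adults replicate 2 to 1.4 in A12 adults replicate 2. In such genes 1 FPKM stood for a median of 9.7 fragments in A4 larvae replicate 1 and 15.3 in A12 adults replicate 2. A further limit is that the labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries. Across genes, which are not independent replicates, libraries of 1 group correlated at 0.957 to 0.967 on the log2 scale. A4 and A12 larvae correlated at 0.845 to 0.893, and A4 and A12 adults at 0.94 to 0.959.

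One larval library carried male-type RNA. In A4 larvae replicate 2, roX2 (X 11473089 to 11474465), an RNA of the male dosage compensation complex, stood at 34.9 FPKM against 0.338 in A4 larvae replicate 1. Its level was 4.65 in A12 larvae replicate 1 and 0.277 in A12 larvae replicate 2. The related RNA roX1 stood at 12.4 FPKM in A4 larvae replicate 2 and at 1.21 to 3.04 in the other larval libraries. Of 47 testis genes, 28 reached 1 FPKM in A4 larvae replicate 2, against 2 to 6 in every other library. Among them were Mst84Dc at 7.67 FPKM and ocn at 6.14, both listed at 0 in the other larval libraries. The roX genes and these testis genes were chosen after their values were seen. In that library 170 genes reached 1 FPKM while staying under 0.1 FPKM in all others, a count that was 5 to 11 for each of the other libraries.

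The first comparison asked which genes differ between A4 and A12 third-instar larvae. Stage within the instar was not recorded in the labels, so different progress through it cannot be told apart from genotype in any larval result. Many genes of digestion, detoxification, muscle and mitochondria stood higher in A4 larvae, and many ecdysone response genes stood lower, as did single genes such as Hsp23, a small heat shock protein gene, and e, a gene of cuticle tanning. The antifungal peptide relative Drsl5 (3L 3316781 to 3317144) fell from 2499.1 ± 804.8 FPKM in A12 larvae to 1.55 ± 0.166 in A4 larvae, a log2 change of -9.90 ± 0.26 (adjusted p = 7.27e-06). In the other direction the maltase gene Mal-A3 (2R 4343414 to 4345390) rose from 2.67 ± 2.84 to 132.3 ± 47.1 FPKM, a log2 change of 5.39 ± 0.53 (adjusted p = 0.000561). In limma, 847 genes rose and 2507 fell in A4 larvae, 3354 of 9679 tested (34.7%). The split depended on the scale, because A4 larval values lay lower as a whole, with a median log2 change of -0.43 over all genes. After median centring 1332 rose and 1005 fell, and after quantile normalization 1124 rose and 1185 fell. List medians are therefore given relative to the median of all genes.

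Many enzymes of digestion and detoxification rose in A4 larvae. Of 44 digestive enzymes tested, 24 rose and 1 fell, 26 and 2 when adjusted over the list alone, with a median of 1.81 (camera adjusted p = 7.21e-15; adjusted p = 0.409 with an estimated correlation). The number that rose was 12 without A4 larvae replicate 2, 13 without A12 larvae replicate 1 and 16 without A4 larvae replicate 1, and without A12 larvae replicate 1 the median was 1.08. The trypsin lambdaTry rose from 0.747 ± 0.74 to 37.5 ± 7.66 FPKM, and its neighbours zetaTry and thetaTry changed by 3.09 ± 0.27 and 2.51 ± 0.25. Of 58 detoxification enzymes, 32 rose and 4 fell, 36 and 5 adjusted over the list alone, with a median of 1.47 (camera adjusted p = 4.48e-17; adjusted p = 0.255 with an estimated correlation). With A12 larvae replicate 1 left out 21 of them rose. The cytochrome P450 gene Cyp6a2 rose from 8.0 ± 1.14 to 81.0 ± 16.7 FPKM, and the glutathione transferase gene GstE6 from 4.92 ± 1.64 to 70.1 ± 21.1. Members of the trypsin and glutathione transferase families are close paralogs, so the share of reads behind each is uncertain.

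Among genes of energy metabolism and muscle more rose than fell. Of 38 lipid and sugar metabolism genes, 13 rose and 7 fell, 18 and 7 adjusted over the list alone (median 0.93, camera adjusted p = 1.17e-05, and adjusted p = 0.183 with an estimated correlation of 0.00507). After median centring 20 rose and 3 fell. Left out singly, A4 larvae replicate 1 gave 9 up and 3 down, A4 larvae replicate 2 gave 12 and 3, and A12 larvae replicate 1 gave 10 and 3. Malic enzyme, Men, rose from 33.8 ± 11.2 to 213.1 ± 0.305 FPKM and aldehyde dehydrogenase, Aldh, from 20.1 ± 10.6 to 204.4 ± 59.1, while the lipocalin gene NLaz fell by 3.43 on the log2 scale, a call lost with larval libraries alone. Of 28 genes of mitochondrial oxidative phosphorylation, 20 rose after median centring and 14 after quantile normalization, and 0 fell. Without such scaling 10 rose and 0 fell, also when adjusted over the list alone, and all 28 lay above the median of all genes (median 1.06, camera adjusted p = 1.99e-11, and adjusted p = 0.305 with an estimated correlation). These calls rested on all larval libraries, since 2 rose without A4 larvae replicate 1, 1 without A4 larvae replicate 2, 2 without A12 larvae replicate 1 and 3 without A12 larvae replicate 2, with medians of 0.92 to 1.23. The succinate dehydrogenase subunit gene SdhA went from 45.9 ± 1.21 to 89.2 ± 2.11 FPKM, a log2 change of 0.94 ± 0.17. Of 28 muscle genes, 12 rose and 2 fell, 15 and 2 adjusted over the list alone (median 1.27; camera adjusted p = 4.13e-08; adjusted p = 0.345 with an estimated correlation). Only 4 rose without A12 larvae replicate 1 and 5 without A4 larvae replicate 1. Troponin C gene TpnC47D rose from 3.46 ± 1.86 to 72.3 ± 15.2 FPKM and the myosin light chain gene Mlc2 from 350.8 ± 104.4 to 1219.5 ± 33.9.

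Cuticle protein genes split. Of 39 larval and pupal cuticle genes, 15 rose and 8 fell in A4 larvae, 19 and 8 adjusted over the list alone (median 1.0; camera adjusted p = 2.93e-08; adjusted p = 0.345 with an estimated correlation). The median was 1.52 without A12 larvae replicate 2. Lcp65Ag3, 1 of several near-identical copies, rose from 0.374 ± 0.000428 to 33.9 ± 6.64 FPKM and Cpr47Ec from 8.45 ± 9.22 to 511.9 ± 141.6. Of 24 eye colour and body colour genes, 2 rose and 13 fell, 2 and 14 adjusted over the list alone (median -0.24; camera adjusted p = 0.0561). After median centring 2 rose and 6 fell, and 5 fell without A4 larvae replicate 1 or A12 larvae replicate 1 and 7 without A4 larvae replicate 2. The gene e (ebony, 3R 17055561 to 17062900), which makes beta-alanyl dopamine for cuticle tanning, fell from 540.9 ± 305.5 to 0.79 ± 0.519 FPKM. The gene b (black), which makes the beta-alanine for that step, fell from 387.9 ± 167.1 to 6.13 ± 3.55 FPKM. The dopamine synthesis genes Ddc and ple, which the neuron list holds, changed by -3.54 ± 0.39 and -4.58 ± 0.80, and Pu, needed for the cofactor of ple, by -2.90 ± 0.26. The change of ple did not pass without A12 larvae replicate 1 or with larval libraries alone.

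Many genes that respond to the moulting hormone ecdysone fell. Of 25 ecdysone response genes, 1 rose and 16 fell, 1 and 17 adjusted over the list alone (median -1.01; camera adjusted p = 0.00338; adjusted p = 0.547 with an estimated correlation). ImpE2 (3L 3510974 to 3512681) fell from 278.5 ± 107.8 to 24.3 ± 4.7 FPKM, ImpE3 changed by -3.70 ± 0.21 and the nuclear receptor gene Eip78C by -4.07 ± 0.44. Of 17 glue and Eig71E genes of the salivary gland, 3 rose and 11 fell, 3 and 12 adjusted over the list alone (median -0.86, camera adjusted p = 0.119, and adjusted p = 0.409 with an estimated correlation). The camera adjusted p was 0.00878 after median centring and 0.0148 after quantile normalization, and the median was -0.57 without A12 larvae replicate 2. Eig71Ea fell from 63.4 ± 8.76 to 0.397 ± 0.102 FPKM, whereas the paralogs ng1 and ng2, expressed before the glue genes, rose by 4.56 ± 0.30 and 4.82 ± 0.33. Of 21 heat shock protein genes, 2 rose and 8 fell, 2 and 9 adjusted over the list alone. The list's median was 0.05 relative to all genes, opposite in sign to its camera test (adjusted p = 0.748), and -0.38 before the shift of all genes was taken off, where the mean was -0.68. Without A4 larvae replicate 1 or A12 larvae replicate 1 the number that fell was 4, and without A12 larvae replicate 2 the median was -0.07. The 2 that rose did not pass without A4 larvae replicate 1, A4 larvae replicate 2 or A12 larvae replicate 2. Hsp23 fell from 3625.6 ± 121.9 to 644.2 ± 81.4 FPKM and Hsp67Bc changed by -3.22 ± 0.20.

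**Figure D1:**
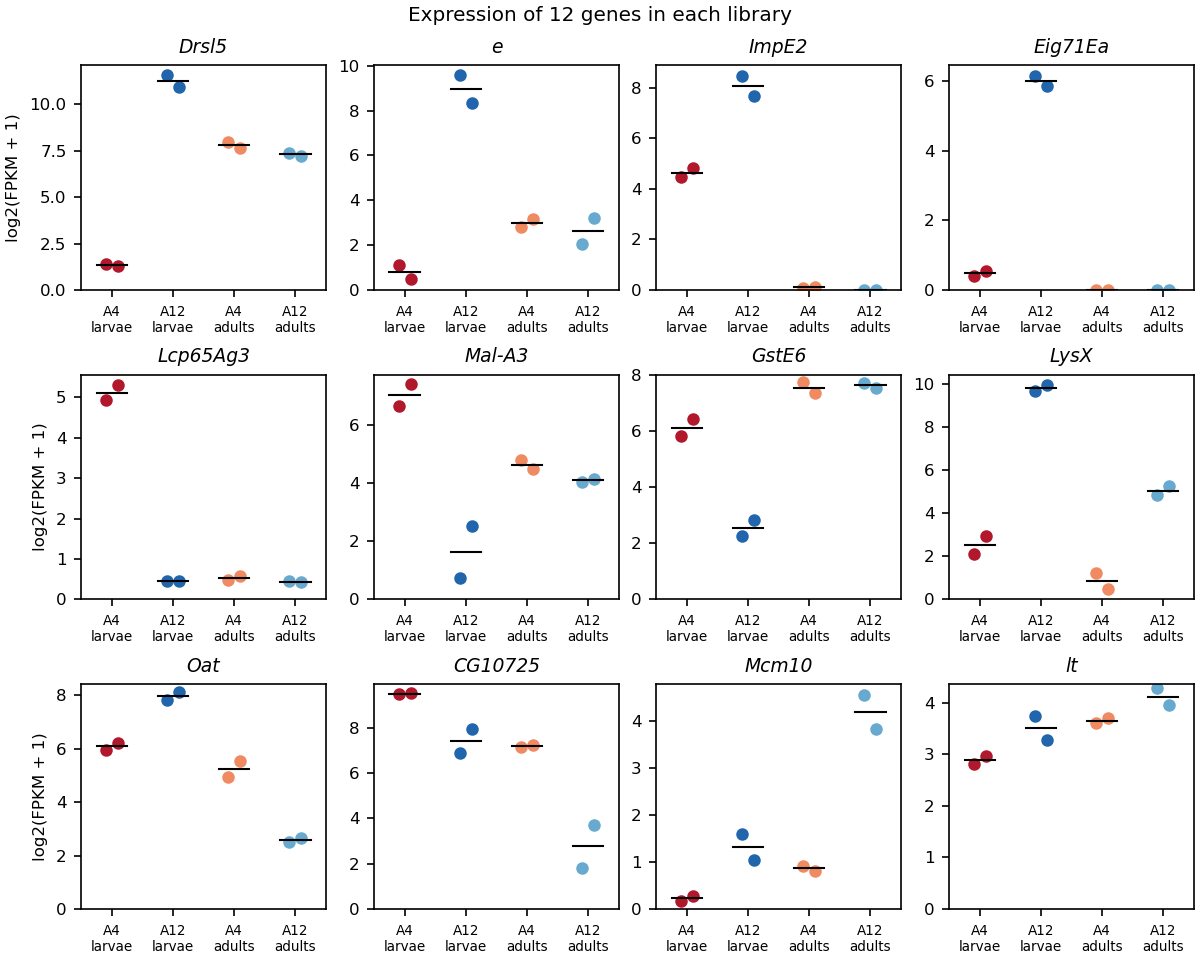
Expression of 12 genes in each of the 8 libraries, as log2(FPKM + 1) on the vertical axis, with 1 point per library, a bar at the mean of the 2 libraries and a group per position on the horizontal axis. Drsl5, e, ImpE2, Eig71Ea and LysX were lower in both A4 larval libraries than in both A12 ones, Lcp65Ag3, Mal-A3, GstE6 and CG10725 were higher, and Mcm10 separated the genotypes most in adults, where it stood at 0.901 and 0.761 FPKM in A4 and 22.8 and 13.3 FPKM in A12.

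Immune genes fell in part. Of 43 genes of antimicrobial peptides and recognition proteins, 0 rose and 11 fell, 0 and 7 adjusted over the list alone. Their median was 0.12 relative to all genes (camera adjusted p = 0.906), and -0.31 before that shift was taken off, where the mean was -0.79. After median centring 1 rose and 5 fell. The number that fell was 6 without A4 larvae replicate 2 or A12 larvae replicate 1, and the median was -0.35 without A4 larvae replicate 1 and -0.27 without A12 larvae replicate 2. Drsl2 fell from 1351.8 ± 495.9 to 29.5 ± 11.1 FPKM and the lysozyme gene LysX, which has close paralogs, from 888.8 ± 129.2 to 5.08 ± 2.41. Among 3 Turandot stress genes 0 rose and 1 fell, also over the list alone, and this was TotA, which fell from 675.7 ± 165.9 to 90.6 ± 16.1 FPKM. The list's median was 1.45 relative to all genes (camera adjusted p = 0.523). Before the shift was taken off, its median was positive and its mean was -0.24. The metallothionein gene MtnC fell from 766.5 ± 77.2 to 3.23 ± 0.156 FPKM. Of 8 larval serum and fat body genes, the storage protein gene Lsp1beta rose from 5914.2 ± 3705.8 to 20353.8 ± 4268.3 FPKM and Lsp2 fell from 22553.8 ± 2500.5 to 10629.2 ± 112.9. Neither call held without A4 larvae replicate 1, A4 larvae replicate 2 or A12 larvae replicate 1, nor Lsp2 after median centring or without A12 larvae replicate 2. Over the list alone 1 rose and 2 fell, and the median of -0.26 was opposite in sign to the camera test (adjusted p = 0.698). That median was 0.45 without A12 larvae replicate 2, 0.01 without A4 larvae replicate 2 and -0.76 without A12 larvae replicate 1.

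In the larval lists nearest to the design's question the calls changed with the scale. Of 44 heterochromatin proteins and modifiers of variegation, 0 rose and 15 fell, 0 and 18 adjusted over the list alone (median -0.22; camera adjusted p = 0.0193; adjusted p = 0.887 with an estimated correlation). After median centring 2 fell and after quantile normalization 3. Without A4 larvae replicate 2, the library with male-type RNA, the list's adjusted p was 0.0922, and without A12 larvae replicate 1 it was 0.0697. The number that fell was 5 without A4 larvae replicate 2 and 1 without A4 larvae replicate 1 or A12 larvae replicate 1. The insulator gene mod(mdg4), present at more than 1 locus in the files, changed by -1.31 ± 0.28 and the histone deacetylase gene Rpd3 by -1.12 ± 0.25. Rpd3 did not pass without A4 larvae replicate 1 or A12 larvae replicate 1, with larval libraries alone, or with replicate number as a block on centred values. The gene of HP1a, a main protein of heterochromatin, went from 49.3 ± 16.1 to 29.0 ± 6.83 FPKM and did not pass (adjusted p = 0.095). Su(var)3-9 was listed at 0 in 7 of the 8 libraries. The same held for Hsc70-4 in 6 libraries and Msp-300 in 5, and a listed 0 can stand for reads given to another gene model. Absence of Su(var)3-9 RNA is therefore not shown. Of 29 genes residing in pericentromeric heterochromatin, 0 rose and 7 fell, also adjusted over the list alone (median -0.30, camera adjusted p = 0.0574, and adjusted p = 0.887 with an estimated correlation). After median centring 1 rose and 5 fell, and the camera adjusted p was 0.0194. The number that fell was 3 with A4 larvae replicate 1 or A4 larvae replicate 2 left out, 2 without A12 larvae replicate 1, where the median was -0.08, and 17 without A12 larvae replicate 2, where it was -0.53. Cht3 (2L 22892306 to 22918647), a chitinase gene, fell from 144.4 ± 34.7 to 43.9 ± 2.22 FPKM, and Yeti, which did not pass with larval libraries alone, from 72.5 ± 22.0 to 24.4 ± 5.29. The classic heterochromatic genes lt (2L 22811944 to 22834955) and rl changed by -0.62 ± 0.22 and -0.71 ± 0.24 without passing (adjusted p = 0.0648 and 0.0565). The pigment transporter gene w changed by -0.70 ± 0.20 (adjusted p = 0.0322), but by -0.25 after median centring, where it did not pass (adjusted p = 0.269).

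The remaining larval lists gave few calls. Of 23 listed genes on chromosome 4, 0 rose and 6 fell, 0 and 10 adjusted over the list alone (camera adjusted p = 0.0574), and 0 fell after median centring. The list is a part of the chromosome, of whose 69 tested genes 15 were called in larvae (21.74%), against 34.7% of all genes. Of 82 cytoplasmic ribosomal proteins 1 fell (camera adjusted p = 0.906), of 22 piRNA pathway genes 1 fell (0.313), of 9 histone genes 1 fell (0.346) and of 22 yolk and eggshell genes 1 fell (0.346), with 0 in each list adjusted over the list alone. Of 33 female germline genes, 2 rose and 4 fell, 2 and 0 adjusted over the list alone (camera adjusted p = 0.422), and 0 fell without A4 larvae replicate 1 or A12 larvae replicate 1 and 1 without A4 larvae replicate 2. Of 25 neuron and eye genes, 0 rose and 5 fell, 0 and 4 adjusted over the list alone (camera adjusted p = 0.728), and 2 fell without A4 larvae replicate 2 and 1 without A12 larvae replicate 1. The ribosomal, piRNA, germline, neuron and eggshell lists had medians of 0.03, 0.43, 0.37, 0.30 and 0.38 relative to all genes, but negative means before the shift of all genes was taken off. The ribosomal median was -0.19 without A4 larvae replicate 2, -0.09 without A12 larvae replicate 1, 0.14 without A12 larvae replicate 2 and 0.23 without A4 larvae replicate 1. The chromosome 4 median of -0.31 was -0.17 without A12 larvae replicate 1 and -0.48 without A12 larvae replicate 2. The histone median of -0.07 was -0.28 without A4 larvae replicate 2, -0.15 without A12 larvae replicate 2 and -0.11 without A4 larvae replicate 1. Testis genes had a median of 1.92 with 0 of 14 past the threshold (camera adjusted p = 0.00498; adjusted p = 0.799 with an estimated correlation), and without A4 larvae replicate 2 their adjusted p was 0.516 and their median 0.46. With A4 larvae replicate 1 left out instead, 9 rose and the median was 3.32. In the list of Y chromosome and dosage compensation genes the tested members were roX1, roX2 and msl-2, and no Y chromosome gene was among them. Their median was 1.53 and 0 of 3 passed in limma (camera adjusted p = 0.346), but 2 rose without A4 larvae replicate 1, and the median was 0.23 without A4 larvae replicate 2 and 0.85 without A12 larvae replicate 2. Of 5 male accessory gland and ejaculatory duct genes 3 rose and 1 fell, also over the list alone (camera adjusted p = 0.0118; adjusted p = 0.345 with an estimated correlation). After median centring the adjusted p of that list was 0.07. The members that rose, Obp56e at 30.4 ± 7.74 FPKM in A4 larvae, Est-6 and PebIII, were expressed in both A4 larval libraries, and without A4 larvae replicate 2 the list again had 3 up and 1 down.

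Further genes with large changes in larvae, apart from e and Drsl5 above, included small nucleolar RNAs and uncharacterized genes. The RNA snoRNA:Psi28S-1135e stood at 7092.8 and 3501.4 FPKM in the A12 larval libraries and at 11.7 and 10.6 in the A4 ones. The RNA snoRNA:Psi18S-1377a was listed at 0 in A4 larvae and stood at 26573.1 and 18721.6 FPKM in A12 larvae, a difference that did not pass after median centring. In A12 adults its values were 0.0 and 47650.4 FPKM. Both RNAs overlap another gene model. CG32198 (3L 18520076 to 18520545) rose from 10.4 ± 13.2 to 2307.4 ± 0.269 FPKM and the neuropeptide-like precursor gene Nplp2 from 14.8 ± 11.8 to 1026.8 ± 399.8. Neighbouring genes CG7924, CG34244 and CG7906, between 3L 14226569 and 14231372, changed together, CG7924 by -9.51 ± 0.33 and CG34244 by -9.37 ± 0.39, and CG7906 went from 754.8 ± 400.3 to 0.412 ± 0.491 FPKM. CG14664 fell from 1833.9 ± 780.0 to 0.302 ± 0.428 FPKM. The libraries of the 2 genotypes did not overlap in 72.6% of all tested genes, against 33.3% by chance. The number of genes past the threshold was 2041 without A4 larvae replicate 2, the library with male-type RNA, 1630 without A4 larvae replicate 1, 1386 without A12 larvae replicate 1 and 1036 when the larval libraries were fitted alone. Of 119 named larval genes at 1 locus that passed, 73 passed under every alternative that tested them, and 40 did not pass in the fit of larval libraries alone. Genes with a 0 in any library were not tested by the fit that left such genes out.

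In adults the genotypes differed in few genes, among them the DNA replication gene Mcm10, lysozymes and serine proteases. Mcm10 (2L 21179941 to 21182812), named because its change stood out after the values were seen, fell from 18.1 ± 6.75 FPKM in A12 adults to 0.831 ± 0.0989 in A4 adults, a log2 change of -3.33 ± 0.31 (adjusted p = 0.00373). The ornithine aminotransferase gene Oat rose from 5.0 ± 0.408 to 37.4 ± 10.9 FPKM and CG10725 from 7.33 ± 6.82 to 146.7 ± 8.27. In limma, 21 genes rose and 50 fell in A4 adults, 71 of 9679. The median log2 change over all genes was -0.05, and the count was 66 after median centring and 68 after quantile normalization. With only the adult libraries in the fit 21 genes passed, and Mcm10, Oat and CG10725 were not among them (adjusted p = 0.125, 0.134 and 0.263). CG10725 did not pass after median centring either (adjusted p = 0.0544), nor without a filter, with robust eBayes, or with any larval library or either A4 adult library left out.

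Protease and lysozyme genes made up part of the adult calls. Send1, a protease gene of the spermatheca, fell from 27.2 ± 9.88 to 3.39 ± 0.116 FPKM, next to CG17239 and CG31681, which changed by -2.33 ± 0.28 and -3.33 ± 0.23. Of 44 digestive enzymes, 0 rose and 2 fell, 2 and 4 adjusted over the list alone. Jon65Aii fell from 186.8 ± 30.8 to 15.7 ± 6.34 FPKM and its neighbour Jon65Ai from 271.6 ± 54.8 to 82.5 ± 7.82. The lysozyme gene LysC stood at 772.2 and 871.1 FPKM in the A12 libraries and at 19.1 and 7.15 in the A4 ones, and LysX and LysB changed by -4.19 ± 0.36 and -3.82 ± 0.56. These neighbours are near-identical copies, so the share of reads behind each is uncertain, and LysB and Jon65Ai did not pass after median centring (adjusted p = 0.0654 and 0.0968). With adult libraries alone 21 of the 34 named adult genes that passed were lost, among them LysB, LysC, LysX, Jon65Ai, Jon65Aii, Send1, CG17239, CG31681, CG1304, Obp99d and CG6071. Of the 34, 11 passed under every alternative that tested them, such as CG43680, CG2118, CG14040 and Arp5. These examples were listed at 0 in adults of 1 genotype, so the fit without genes listed at 0 did not test them. Nor did the filter at a mean of at least 5 FPKM test CG14040. Of 43 antimicrobial and recognition genes, 0 rose and 2 fell, LysX and LysB, 1 and 2 adjusted over the list alone (camera adjusted p = 0.0824). In both of these lists 1 fell with any single adult library left out. CG1304, a protease gene of the X chromosome, rose from 1.01 ± 0.41 to 25.3 ± 1.71 FPKM, the odorant-binding protein gene Obp99d was at 0.0 and 0.492 FPKM in the A12 libraries and 6.33 and 11.4 in the A4 ones, and CG6071 changed by 2.22 ± 0.23.

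Many adult calls were genes listed at exactly 0 in a whole genotype, 24 of the 71. CG43680 was listed at 0 in A4 adults and stood at 147.7 and 222.9 FPKM in the A12 libraries. CG2118, Art8, CG14701 and muted were likewise listed at 0 in A4 adults, and CG12204, CG14040, crim, Arp5 and CG2909 in A12 adults. Art8, an arginine methyltransferase gene, stood at 23.8 and 15.2 FPKM in the A12 libraries, and CG14040 at 15.6 and 14.3 in the A4 ones. CG43680, CG2118, Art8, CG14701, muted, CG12204, CG14040, crim, Arp5 and CG2909 all overlap another gene model, so an assignment of shared reads to that other model is not excluded. The small nucleolar RNA snoRNA:Psi28S-1135e was listed at 0 in A4 adults too and stood at 4642.0 and 8909.1 FPKM in A12, and the same holds for it.

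By camera with its preset correlation, some adult lists showed small shared shifts without single genes passing over all genes. No adult list passed with an estimated correlation (camera adjusted p = 0.998 for each). Nor did any pass by fry, a further list test in limma, whose adjusted p ran from 0.638 to 0.9. All 29 genes residing in pericentromeric heterochromatin lay below the median of all genes in A4 adults, with a list median of -0.41 and 0 past the threshold, also adjusted over the list alone (camera adjusted p = 3.49e-05; adjusted p = 0.998 with an estimated correlation). Among them lt went from 16.5 ± 2.85 to 11.6 ± 0.564 FPKM (log2 change -0.46 ± 0.22, adjusted p = 0.512) and rl from 20.2 ± 3.18 to 12.8 ± 1.78 (-0.62 ± 0.24, adjusted p = 0.438). The 44 heterochromatin proteins and modifiers of variegation had a median of 0.30 (camera adjusted p = 0.000286; adjusted p = 0.998 with an estimated correlation), and without A12 adults replicate 2 the camera adjusted p was 0.276 and the median 0.12, against 0.48 without A12 adults replicate 1. The 22 yolk and eggshell genes had a median of 0.59, with 2 past the threshold adjusted over the list alone (camera adjusted p = 1.87e-06; adjusted p = 0.998 with an estimated correlation). Their median was 0.32 without A4 adults replicate 1 and 1.04 without A4 adults replicate 2. The chorion gene Cp19 stood at 1578.6 ± 627.4 FPKM in A4 and 391.3 ± 58.1 in A12 adults (adjusted p = 0.158). The 28 genes of oxidative phosphorylation had a median of -0.27 (camera adjusted p = 0.00354; adjusted p = 0.998 with an estimated correlation), with an adjusted p of 0.471 after quantile normalization and 0.515 without A12 adults replicate 2, where the median was -0.07, against -0.52 without A12 adults replicate 1. In limma 0 members of the other 19 lists passed over all genes, while 1020 of all tested genes had an unadjusted p under 0.05. The camera adjusted p of these 19 lists ran from 0.0594 for muscle genes to 0.995 for ecdysone response genes. For digestive enzymes, which are not among the 19 because 2 fell, it was 0.898. Adjusted over the list alone, 1 male accessory gland gene rose and 3 fell, and 1 ecdysone response gene fell. Without A12 adults replicate 1, the median of the pericentromeric list was -0.28, with 22 of its 29 members below the median of all genes.

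**Figure D2:**
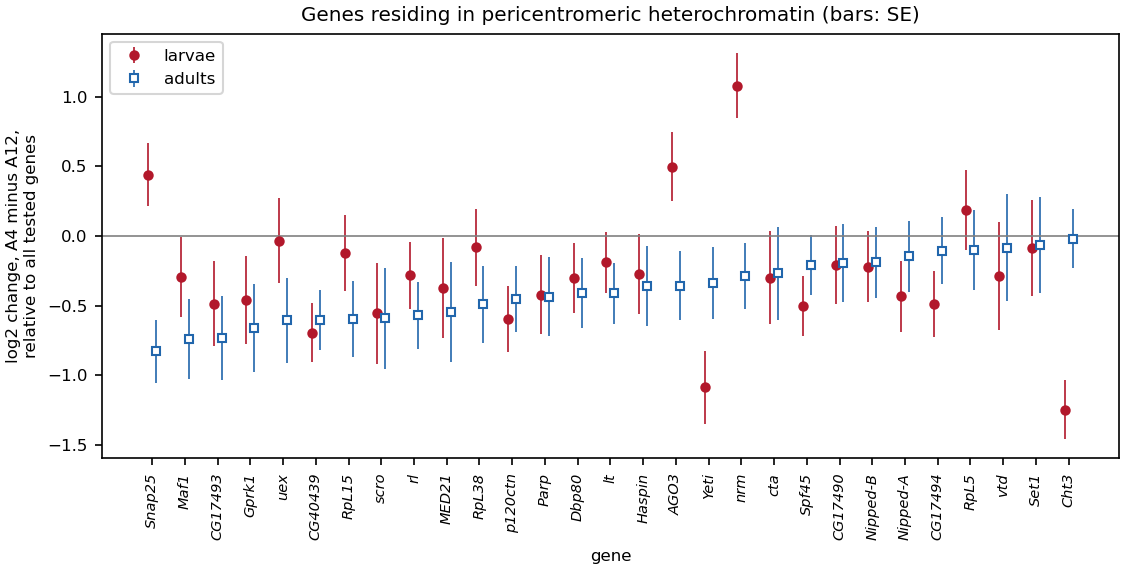
Log2 change between A4 and A12 of 29 genes residing in pericentromeric heterochromatin, relative to the median of all tested genes, with 1 gene per position on the horizontal axis, circles for larvae, squares for adults and bars for the standard error. All 29 squares lie below 0, around a median of -0.41, and 25 of the 29 circles do too, around a median of -0.30.

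A direct test of whether the genotype difference changed between the stages gave 1704 genes past the threshold. The difference was more positive in adults for 1051 of them and more negative for 653, and after median centring for 616 and 923. Among the 8 with the smallest adjusted p, Drsl5 moved by 10.42 ± 0.37 and CG7924 by 10.08 ± 0.46, both far below A12 in A4 larvae and near it in A4 adults. CG10219 (3R 19585205 to 19586322) was listed at 0 in A12 larvae, stood at 60.7 and 55.8 FPKM in the A4 larval libraries, and was at 178.5 and 178.5 in A4 and 262.5 and 262.5 in A12 adults. CG12272 was listed at 0 in A4 larvae and in A12 adults, against 14.0 and 13.6 FPKM in A12 larvae and 7.76 and 8.36 in A4 adults. Both overlap another gene model. In the interaction the lists that had risen in larvae moved down, among them 17 of 44 digestive enzymes with 0 moving up (camera adjusted p = 5.23e-12; adjusted p = 0.515 with an estimated correlation) and 22 of 58 detoxification enzymes with 2 moving up (camera adjusted p = 1.31e-13; adjusted p = 0.303 with an estimated correlation). The number of digestive enzymes moving down was 7 without A4 adults replicate 2, 8 without A4 larvae replicate 2, A4 adults replicate 1 or A12 adults replicate 2, 10 without A12 adults replicate 1, and 11 without A4 larvae replicate 1 or A12 larvae replicate 1. Their median relative to all genes, -2.21, was -1.31 without A12 larvae replicate 1. The number of detoxification enzymes moving down was 13 without A4 adults replicate 1, A4 adults replicate 2 or A12 adults replicate 2, and 14 without A4 larvae replicate 2 or A12 larvae replicate 1. Leaving out A4 adults replicate 2 lowered the number of genes to 637, and the value was 649 without A4 adults replicate 1, 745 without A12 adults replicate 2, 830 without A12 larvae replicate 1, 890 without A4 larvae replicate 1 and 1049 without A4 larvae replicate 2.

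A small set of genes differed in the same direction at both stages. LysX and LysC fell in A4 larvae and adults, and CG1304 and CG3588 rose in both. CG3588 (X 2813803 to 2818459) went from 0.17 ± 0.131 to 98.9 ± 15.9 FPKM in larvae and from 0.11 ± 0.00872 to 4.23 ± 0.762 in adults. In all, 27 genes passed at both stages with the same sign, 7 higher and 20 lower in A4, where 14.8 were expected by chance (odds ratio 1.64 over the 33 genes of either sign, two-sided Fisher's exact test, p = 0.0445). The comparisons share 1 estimate of the spread, which can by itself enlarge the overlap. With each stage fitted alone 4 genes were shared (Fisher's exact p = 0.0663), CG7408, CG9766, CG31219 and snoRNA:Psi28S-1135e, while LysX, LysC, CG1304 and CG3588 did not pass in adults, nor CG3588 at a pseudocount of 5. Otherwise the count was 16 without a filter on low values, 16 with a mean of at least 5 FPKM and 13 to 23 with 1 library left out. The lowest of those came without A4 adults replicate 2. CG7408, listed at 0 in A4 at both stages, stood at 5.75 and 6.92 FPKM in the A12 larval libraries and at 9.27 and 8.64 in the A12 adult ones. It overlaps another gene model, as does CG3588.

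**Figure D3:**
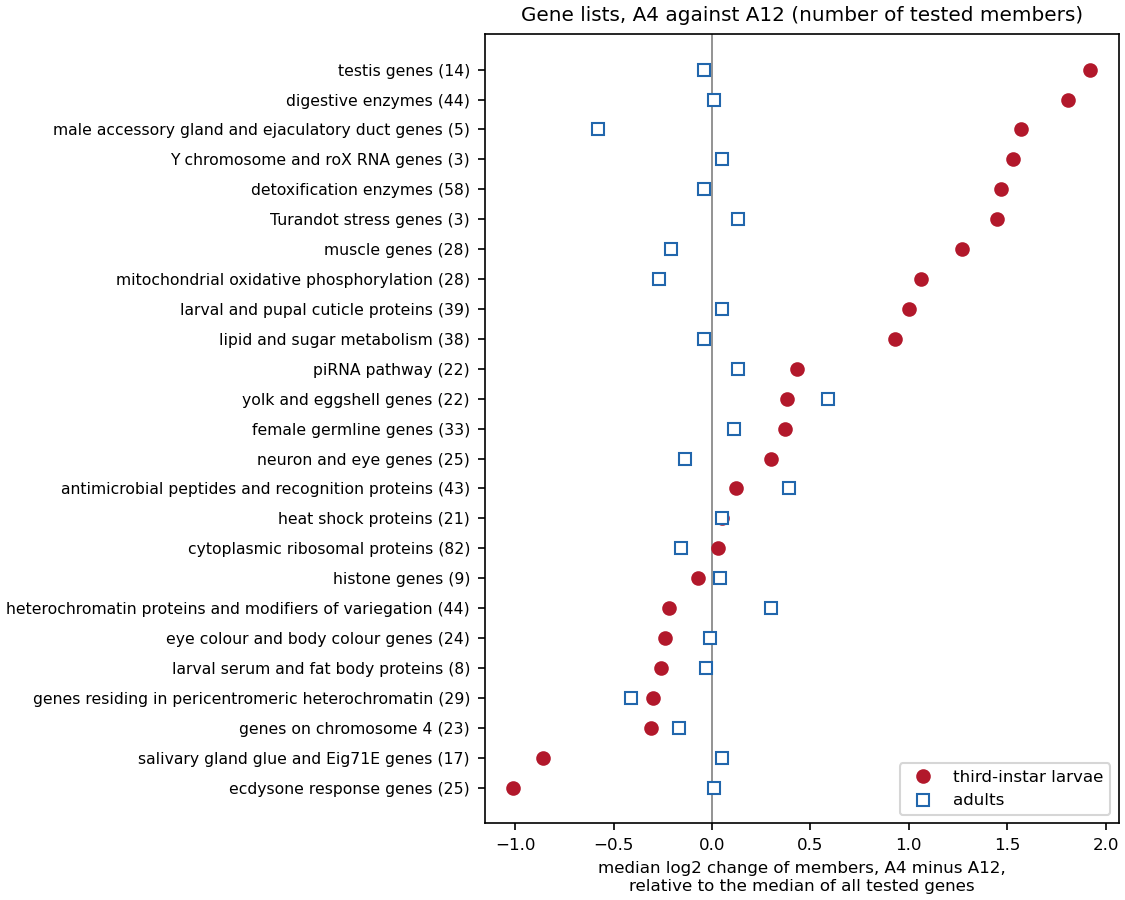
Median log2 change between A4 and A12 of 25 gene lists, relative to the median of all tested genes, on the horizontal axis, with 1 list and its number of tested members per line, circles for larvae and squares for adults. Larval medians run from -1.01 for ecdysone response genes to 1.92 for testis genes, which are expressed in 1 of the 2 A4 larval libraries, and adult medians from -0.58 to 0.59.

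Because In(2)A4 rearranges chromosome 2, called genes were counted by chromosome. Genes on 2L and 2R were called less often than the pooled genes of X, 3 and 4. By arm, the larval share was 33.88% on 2L and 32.36% on 2R. It was higher on 3L (37.32%) and 3R (36.97%), lower on chromosome 4 (21.74%), and on X (32.54%) between 2R and 2L. In adults 2L (0.35%) and 2R (0.2%) lay below every other arm (0.67% to 1.45%). In larvae 1233 of 3730 genes on chromosome 2 passed and 2108 of 5899 on X, 3 and 4, an odds ratio of 0.888 (Fisher's exact test, two-sided, p = 0.00734). By Fisher's exact test that difference did not pass after median centring (0.911, p = 0.0602), after quantile normalization (0.908, p = 0.0527) or with larval libraries alone (0.9, p = 0.129). In adults 10 of 3730 genes on chromosome 2 passed and 60 of 5899 elsewhere, an odds ratio of 0.262 (Fisher's exact test, p = 1.06e-05). By the exact test it was, with adult libraries alone, 0.494 (p = 0.184), without A4 adults replicate 1 0.739 (p = 0.266), without A4 adults replicate 2 0.862 (p = 0.667) and without A12 adults replicate 1 0.764 (p = 0.245).

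Runs of neighbouring called genes were sought along each arm. In larvae 11 of 11 neighbouring genes were called at the Enhancer of split complex (3R 21823343 to 21875633), a set of Notch target genes. Of these, 10 were lower in A4 larvae, such as E(spl)m7-HLH at 14.3 ± 1.48 FPKM in A12 and 4.5 ± 0.732 in A4, E(spl)m2-BFM (-2.03 ± 0.44) and the co-repressor gene gro, at 12.7 ± 1.71 and 5.83 ± 0.719 FPKM. Kaz-m1, a protease inhibitor gene, rose from 93.0 ± 44.6 to 359.8 ± 26.8 FPKM. The window was 1 of 3 with 11 calls, and in the permutation test p was 0.0583. Of its 11 genes 8 were lost after median centring or without A12 larvae replicate 1, 7 after quantile normalization or without A4 larvae replicate 1, and 10 with larval libraries alone, where E(spl)m7-HLH alone passed. In adults the largest number was 3 of 11, in 22 windows (permutation p = 0.229), the first of which held CG17239, Send1 and CG31681 (2L 2214266 to 2286873), all of them lost with adult libraries alone.

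Between the stages, within each genotype, yolk, eggshell and germline genes rose in adults and larval genes fell. In A12 females Yp3 went from 4.01 ± 0.371 FPKM in larvae to 3794.5 ± 2.98 in adults, the yolk receptor gene yl from 0.433 ± 0.135 to 432.5 ± 73.6 and the opsin gene ninaE from 0.476 ± 0.437 to 683.6 ± 67.6. The glue gene Sgs7, which has close paralogs, fell from 26967.7 ± 7801.2 to 10.8 ± 1.88 FPKM and the storage protein gene Lsp2 from 22553.8 ± 2500.5 to 10.4 ± 1.7. In A12, 3974 genes rose and 1701 fell in adults, and after median centring 2713 and 2758. In A4, 5397 rose and 1345 fell, and after median centring 2497 and 2724. All 22 yolk and eggshell genes rose in both genotypes, as did all 28 genes of oxidative phosphorylation, and 27 of 33 female germline genes rose in A12 and 32 in A4. After median centring 21 and 22 yolk and eggshell genes, 28 and 21 genes of oxidative phosphorylation and 27 and 26 germline genes rose in A12 and A4. Of 17 glue and Eig71E genes 16 fell in A12 and 11 in A4, and after median centring 17 and 16. The camera call for glue and Eig71E genes was the one call in any comparison that held with an estimated correlation (adjusted p = 0.0271 in A12 and 0.0332 in A4). The estimate for that list was -0.0236, below the preset, so this does not show that the call withstands correlation between members. More heat shock genes fell than rose in both genotypes, 12 of 21 with 3 risen in A12 and 12 with 6 risen in A4, and 20 of 22 piRNA pathway genes rose in both. In A4 the larval cuticle gene Lcp4 fell from 18140.7 ± 2854.6 to 3.74 ± 0.111 FPKM and the protease gene Jon66Ci from 7062.5 ± 1199.0 to 5.41 ± 0.26, while the yolk gene Yp1 rose from 0.783 ± 0.0845 to 2274.1 ± 803.6.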

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

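The tests of an offset in scale, of male RNA, of progress through the third instar and of a single library were chosen only after the result was seen.

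The genotype difference changed between larvae and adults in 1704 genes by the interaction test in limma, and 8 of them are named for it. On the log2(FPKM + 1) scale the adult difference minus the larval one was 10.42 for Drsl5, 10.08 for CG7924, 7.07 for CG12272 and 6.68 for CG32762. It was -6.44 for CG10219, -6.2 for CG3814, -5.79 for CG13230 and -7.97 for CG43680. CG12272, CG32762, CG10219, CG3814 and CG13230 were listed at 0 in a whole larval group, and CG43680 in A4 adults, so these values are no folds.

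The first pattern is the wide larval difference, 3354 genes. An offset of the A4 larval libraries on the FPKM scale does not account for all of it, since after median centring 55.2% of the calls, 1850 genes, passed with the same sign. Nor does male RNA in A4 larvae replicate 2, since without that library 55.6%, 1865 genes, passed with the same sign. Different progress of the larvae through the third instar and genotype cannot be told apart, because stage within the instar was not recorded in the labels. The genes ng1 and ng2, expressed before the glue genes, rose in A4 larvae. Of 17 glue and Eig71E genes 3 rose and 11 fell, and of 25 ecdysone response genes 1 rose and 16 fell. A test by correlation did not decide the question. Across genes, A12 larvae replicate 1 minus 2 correlated with A4 minus A12 at -0.36 (Spearman -0.47), below the bound of -0.2. Over 8912 genes above 0 in all larval libraries the Pearson value was -0.5. The medians of the 25 gene lists gave -0.35 (Spearman -0.43), short of their bound of -0.5. The gene correlation for the A4 larval libraries was -0.01. Noise in A12 larvae replicate 1 alone gives the same sign, and an effect of the rearrangement itself stays open and untested.

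The second pattern is the genes listed at exactly 0 in 1 genotype and at 10 FPKM or more in the other, 33 in larvae and 15 in adults. Of these 48 genes 45 overlap another gene model (93.8%), against 43.6% of the other tested genes (odds ratio 19.4, Fisher's exact p = 2.19e-13). This is consistent with reads of overlapping models being given to a single model in some libraries. It does not cover CG32762, CG42815 and PGRP-SB2, which overlap no other model and were listed at 0 in larvae of 1 genotype. The 48 genes include small RNA genes, which made up 317 of the 9679 tested. The overlap was not computed without them, so their part in the odds ratio is unknown. A true loss of expression in single genes of the list was not tested and stays open.

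The third pattern is the lower level of pericentromeric genes in A4 adults, with all 29 members below the median of all genes. Against long gene loci as the cause, the list median of -0.46 lay at percentile 0.01, the smallest that 10000 lists matched on expression and locus length can give. Their middle 95% ran from -0.13 to 0.20, so genes of like length and expression did not share the shift. The matched lists were random draws, whereas members of this list moved together, with an estimated correlation of 0.662. The percentiles therefore do not measure how unusual a shift of the whole list is between 2 and 2 libraries. In larvae the median of -0.72 lay at percentile 8.23, within -0.79 to -0.36, so length together with expression is not excluded for the larval shift. Among lists matched on expression alone the larval median lay at percentile 0.39, outside -0.65 to -0.18. Against a single library making the whole shift, the median relative to all genes stayed at -0.28 or lower with any adult library left out. It was weakest without A12 adults replicate 1, where 22 of 29 members lay below. The list differed by 0.25 between the A12 adult libraries, so the size of the shift is uncertain. With 2 libraries per genotype, a shift of the whole list through variation between libraries is not excluded. The camera call had an adjusted p of 0.998 with an estimated correlation, and the adjusted p of fry was 0.638. The difference between stages was not past the threshold (camera adjusted p = 0.934). An effect of the inversion on heterochromatic genes is a candidate explanation, found and tested on the same data, and a difference between the strains at these loci was not tested.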

How the results depend on the processing

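The fits without genes listed at 0, without small RNA genes and with the block on centred values were chosen only after the result was seen. Of 8445 alternative values for 412 named-gene results, 7961 kept direction and side of the threshold, 420 lost and 62 gained the call, and 2 reversed. For 75 list results, 742 of 825 held, 41 lost, 41 gained and 1 reversed. The reversals were RpL23A between A4 stages, -0.063 after median centring and -0.063 with block and centring, and the ribosomal list in the interaction after quantile normalization (adjusted p = 0.0207). The larval count of 3354 was 1036 with only the compared groups and 2034 with a 2-fold limit, and 1386 to 3385 with 1 library left out. The adult count of 71 was 42 at a mean of at least 5 FPKM and 21 with only the compared groups, and 51 to 96 with 1 library left out. The interaction count of 1704 was 2842 at an adjusted p under 0.1 and 637 to 1880 with 1 library left out. The stage counts ran from 4562 to 5528 in A12 and 5497 to 6856 in A4 with 1 library left out. A lone library was assumed to vary like the other groups. The 27 genes of both stages became 16 without a filter, 16 at a mean of at least 5 FPKM, 4 with only the compared groups, 47 at an adjusted p under 0.1, and 13 to 23 with 1 library left out. The larval odds ratio of chromosome 2, 0.888, was 0.911 with median centring, 0.908 with quantile normalization, 0.919 with robust eBayes, 0.9 with only the compared groups, 0.948 without genes listed at 0 and 0.924 without small RNA genes, none past 0.05, and 0.885 to 0.965 with 1 library left out. The adult one, 0.262, was 0.494 with only the compared groups and 0.358 to 0.862 with 1 library left out. The most larval calls in any window of 11 genes, 11, passed the permutation test at a pseudocount of 5 (11), without a filter (10), with quantile normalization (10), without trend (11), with only the compared groups (9), with block and centring (11) and without A4 larvae replicate 1, A4 larvae replicate 2 or A12 larvae replicate 1 (10 each), but not with another library left out. The window with that number need not be the one at the Enhancer of split complex, of whose 11 genes 1 passed with only the compared groups, 3 with median centring, 3 with block and centring and 4 with quantile normalization. The most adult calls in any window, 3, became 2 to 3 with 1 library left out, and passed without A4 adults replicate 2. Replicate number as a block gave 3600 genes in larvae and 59 in adults, but the replicates were not paired. Stricter thresholds, filters and smaller fits move counts by construction, and for the others the cause was not tested. Depth limits genes of low FPKM, where 1 FPKM stood for 9.7 to 15.3 fragments.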

Other observations

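The reading of Mcm10 and its neighbours and of genes near the centromeres was chosen only after the result was seen, while the gene lists were written before. Mcm10, which loads replication factors, stood lower in A4 adults, at 0.901 and 0.761 FPKM in A4 adults and 22.8 and 13.3 in A12 adults. Its change in larvae was -1.10 ± 0.31 (adjusted p = 0.033), which did not pass after median centring, with larval libraries alone, at a pseudocount of 5, at a mean of at least 5 FPKM, or without A4 larvae replicate 1, A4 larvae replicate 2, A12 larvae replicate 1 or either A4 adult library. Genes beside it on 2L did not move with it in adults, with bur at 0.11 and clumsy at -0.04 on the log2 scale. Mcm10 overlaps 1 other gene model, and the breakpoints of In(2)A4 are not given in the sources used here.

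The genes e, b, Pu, Ddc and ImpE2 fell in A4 larvae under every alternative that tested them, and lambdaTry, Mal-A3 and TpnC47D rose under every alternative that tested them. The dopamine gene ple did not pass without A12 larvae replicate 1 or with larval libraries alone.

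In A4 adults genes within 1 Mb of the proximal end of 2L, 2R and 3L, as mapped in dm3, had lower medians than their arms. Those on 2L include lt and Cht3 of the pericentromeric list, so this partly repeats the reading of that list. The medians of 24, 18 and 6 genes were -0.29 against -0.07 on 2L, -0.41 against -0.06 on 2R and -0.55 against -0.02 on 3L (one-sided exact p = 0.025, 0.0199 and 0.0111). None passed after adjustment over 10 tests (adjusted exact p = 0.0625 for each), and on 3R and X the exact p was 0.627 and 0.285. In larvae the median was -0.75 against -0.41 on 2R (exact p = 0.0224, adjusted 0.0625) and -0.64 against -0.43 on 2L (exact p = 0.0821). On 3R, 3L and X the larval exact p was 0.217, 0.57 and 0.949, with medians above those of the arm on 3L and X.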
